A study of Arabidopsis thaliana with 2 samples.

How the data were processed

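The samples were Arabidopsis thaliana plants grown in pots of soil mixture at 23 °C and 60% humidity and watered, from day 21 and for 10 days, with either 0 or 1400 mg/L kanamycin, per the labels and the design text. Kanamycin is an aminoglycoside antibiotic that acts on bacterial-type ribosomes, which plastids and mitochondria also contain. The design text says that RNA was pooled from the leaves of the 12 plants in a pot, whereas the tissue label reads seedlings, so the organ is given here only as far as those statements go. The design text also names doses of 350 and 700 mg/L, which are not analysed here. There was 1 array for the control and 1 for kanamycin, and each group was taken from its treatment label.

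Each sample was hybridised to a 1-colour Agilent Arabidopsis array with 45220 features and 60-nt probes. The labels state that total RNA was copied into double-stranded cDNA before labelling. The submitters' processing notes and the file headers name Agilent Feature Extraction 10.5.1.1 as the image analysis software. The deposited scanner files hold a processed intensity per spot, already corrected for background by that software per the file headers, and not scaled between arrays. The authors' value table holds the same intensity values, equal within a relative tolerance of 1e-05 at 45220 of 45220 features on both arrays, so using it amounts to omitting the scaling between arrays. No column of a sample was left unused, with 0 such columns.

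Here, log2 of the processed intensity was taken and the 75th percentile over the non-control spots was subtracted on each array. Control spots and spots that the software called outliers (38 on the control array and 47 on the kanamycin array) were left out. No non-control spot was saturated on either array, with 0 on each. Spots of 1 probe were averaged, a probe entered when it was well above background on both arrays, and the value of a gene is the median over its probes. The difference is always kanamycin minus control on the log2 scale. A gene whose probes were well above background on 1 array only was given a lower bound: its scaled signal there against the higher of the lowest signal among probes well above background on the other array and the probe's own signal there. Such values are written "at least N-fold".

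Probes were named through the RefSeq gene table of the assembly TAIR10.1, used for names only. Of the 43603 distinct probes, 34358 matched through the RefSeq accession of the array design, 2137 more through a locus used as gene name and 169 through another accession, while 6939 were left without a locus. Positions are those of the array files, whose headers name the build ath1:Jan2004.

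With 1 array per group there are no replicates, so no p-value or standard error between plants was computed, and a difference has no replicate check. The number of arrays limits the precision. The arrays sat on different slides, so batch and group cannot be told apart. Technical error came from 3 sources: the scanner-model error that the software gives with each signal, the spread between spots of 1 probe, and the spread between probes of 1 gene. The errors quoted with single genes below are the scanner-model errors of the log2 difference. They took nearly the same value, 0.20, for most named genes, so they are not a spread measured for each gene.

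Genes were counted at 2-fold in each direction. There were 31 gene lists fixed before the data were examined, and for those with at least 3 measured members the median difference was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins. A list is said to stand apart when its median lies below percentile 2.5 or above 97.5, which about 5 in 100 lists would do by chance. The percentile describes these 2 arrays and is not a test, since random lists ignore that genes of a pathway move together. The named genes followed a rule fixed at the same time: the 10 highest and the 10 lowest genes with a mean level at or above the median gene and all probes in the same direction, up to 3 highest and 3 lowest members of each list, a fixed set of genes tied to kanamycin transport, plastids, iron and defence, and up to 5 genes each way among those detected on 1 array only. Genes outside that rule are introduced as chosen after their values were seen.

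The alternatives were normexp background correction (offset 50) with limma 3.58.1 under R 4.3.3, followed by quantile normalization or by the 75th percentile, median scaling, a lowess fit on level, no scaling, no filter on dim probes, brighter probes only, saturated spots left out, other ways to combine probes, and thresholds of 1.5-fold and 4-fold. Added after seeing the data were scaling on the E1A spike-in RNAs, and a length adjustment, in which a lowess curve (span 0.3) of the difference on the log2 position of the gene's farthest probe along its transcript was subtracted. Of the 20291 genes measured on both arrays, 20286 have such a position in the array files, which stands in for transcript length. The spike-ins used for scaling had a median log2 difference of 0.36 between arrays, against 0.44 for the 75th percentile. Taking plastid and mitochondrial genome probes by the chromosome that the array file gives was also decided after seeing the data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and statsmodels 0.14.6 did the remaining steps, and matplotlib 3.10.9 drew the plots.

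The gene count and the list percentile were tested on simulated data for this comparison of 1 array against 1, over 21609 genes. With 200 genes moved by 2 on the log2 scale and a noise SD of 0.3, 100% of those moved up and 100% of those moved down were recovered, and 16 other genes passed 2-fold. A list of 20 genes moved by -0.8 came out at percentile 0, and 4 of 100 lists with no change stood apart. The simulated noise was drawn independently for each spot, with no length trend. Across the real arrays the SD of gene differences was 1.01. The simulated figures therefore check the calculation and do not give the rate of false calls in the real comparison.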

Results

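Gene expression was measured in Arabidopsis plants watered with 1400 mg/L kanamycin for 10 days and in plants that received 0 mg/L, each as 1 pooled RNA sample on 1 array. The question set by the design is which transcripts differ between plants under the antibiotic and untreated plants. On the control array 78.7% of the 43803 non-control spots were well above background, and on the kanamycin array 74.0% were. The 75th percentile of the processed intensity was 4668 on the control array and 6346 on the kanamycin array, a log2 difference of 0.44 that the scaling removed. The kanamycin array had the noisier background, with an SD of 6.07 intensity units over its negative control spots against 3.93 on the control array.

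Transcript levels differed widely between the 2 arrays, with genes of jasmonate and ethylene signalling, detoxification and glucosinolate synthesis higher on the kanamycin array and genes of the plastid lower. Of 20291 genes measured on both arrays, 2628 (13.0%) were at least 2-fold higher and 2519 (12.4%) at least 2-fold lower on the kanamycin array. The larger differences were mostly upward: 759 genes were at least 4-fold higher and 164 at least 4-fold lower. These counts leave out 1309 genes well above background on the control array only and 454 on the kanamycin array only. With only brighter probes kept, 950 genes were at least 2-fold higher and 1315 at least 2-fold lower. For comparison, the pooled SD of the log2 difference between spots of 1 probe was 0.11 over 18 replicated probes, and that between probes of 1 gene was 0.31 over 6189 genes with several probes. The median scanner-model error of a gene's difference was 0.20. These spreads come from the same 2 arrays and hold no spread between plants, extractions or slides. They therefore do not show how many genes would pass 2-fold between untreated pots. The split between directions depends on the scaling: without scaling, which moved the median of all genes to 0.49, 5434 genes were higher and 902 lower, so that 85.8% of the genes past 2-fold were higher against 51.1% with scaling. The difference also followed transcript length. Across genes, which are not independent replicates, its Spearman rho with the position of the gene's farthest probe along the transcript was -0.49 (20286 genes), and with that trend subtracted 2217 genes were higher and 1489 lower. For this reason a length-adjusted median is given beside each list that stands apart.

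**Figure D1:**
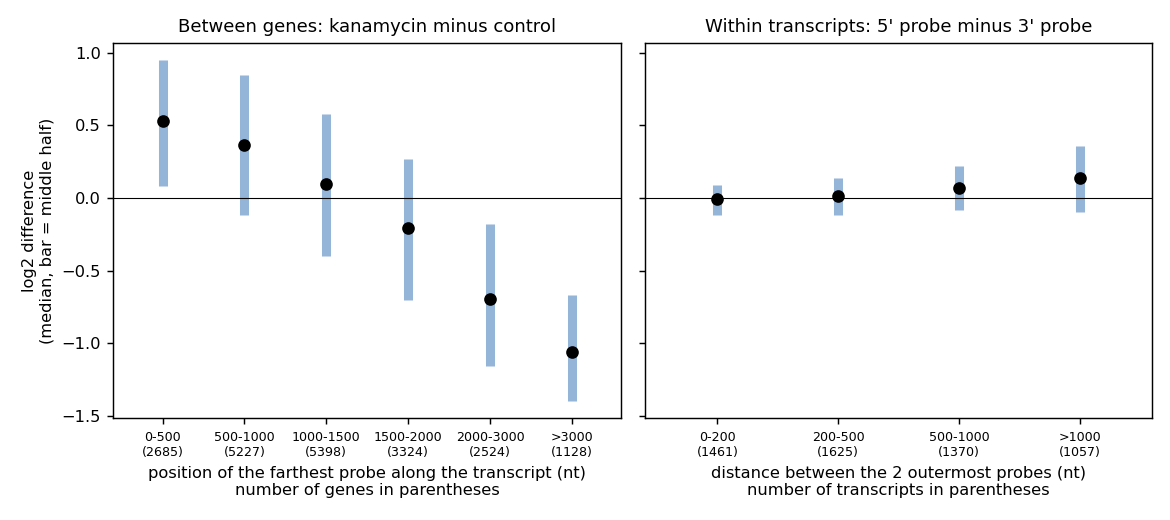
Left, the log2 difference between kanamycin and control for genes grouped by the position of their farthest probe along the transcript (in nucleotides). Right, the difference at the 5' probe minus that at the 3' probe within 1 transcript, by the distance between both probes. Points are medians and bars span the middle 50% of genes or transcripts. The gene median falls from 0.53 in the shortest class to -1.06 in the longest, whereas within transcripts it lies at 0.14 for probes over 1000 nt apart.

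The highest gene that met the naming rule was DR4 (AT1G73330), a protease inhibitor gene, whose scaled signal was 572-fold higher on the kanamycin array (log2 difference 9.16, error 0.22). Its brightest probe lies on chromosome 1 at 27572690 to 27572749 (build ath1:Jan2004), and its 2 probes differed by an SD of 0.13. ADH1 (AT1G77120), the alcohol dehydrogenase of fermentation, was 48.7-fold higher over 3 probes (5.61, error 0.20, chromosome 1, 28982022 to 28982081). The noncoding RNA AT1G11185 was 85.3-fold higher and the dark-inducible oxidoreductase gene DIN11 was 32.2-fold higher. AACT1, an acyltransferase gene, was 24.5-fold higher, and AT3G53980, of the lipid transfer protein family, 23.9-fold higher. The indole glucosinolate methyltransferase gene IGMT3 was 23.2-fold higher, the acetyltransferase gene NATA1 21.9-fold higher and ERF1, an ethylene response transcription factor gene, 20.1-fold higher. IGMT3 has close paralogs whose transcripts could bind its probe, so its value is uncertain. The glycine-rich protein gene GRP9 was 21.9-fold higher, but its 2 probes disagreed with an SD of 3.49.

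Among the lowest genes, 3 belong to flavonoid synthesis. The flavonol synthase gene FLS1 (AT5G08640; chromosome 5, 2805113 to 2805172) was 7.16-fold lower on the kanamycin array (-2.84, error 0.20). The 4-coumarate-CoA ligase gene 4CL3 was 6.38-fold lower, and CHS (AT5G13930), which encodes chalcone synthase, the entry enzyme of the pathway, was 6.23-fold lower. The glutaredoxin family gene AT2G47880 was 6.74-fold lower, the protein phosphatase 2C gene AT5G02760 5.88-fold lower, and HBI1, a bHLH transcription factor gene tied to growth, 5.55-fold lower. MFP1, whose product binds DNA at plastid membranes, was 5.53-fold lower (-2.47, length-adjusted -1.83), and the carboxypeptidase gene BRS1 5.34-fold lower. AT1G13650 (6.69-fold lower) and AT5G16030 (6.35-fold lower) have no described function in the array files. The size of the differences is smaller on this side, and 1 probe stands behind each of these values except that of AT5G16030.

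Nuclear genes for photosynthesis were lower on the kanamycin array by small and similar amounts. All 18 measured light-harvesting genes were lower, with a median of -0.53 (percentile 0.11), from LHCB2.3 at -1.17 and LHCA6 at -1.05 to LHCB2.1 at -0.16. All 27 genes of the photosystems and electron transport were lower, with a median of -0.48 (percentile 0.04), and none reached 2-fold: the range ran from PSAD1 at -0.85 to PSAH1 at -0.20. All 17 Calvin cycle genes were lower, with a median of -0.49 (percentile 0.26), led by PRK, which encodes phosphoribulokinase, at -1.30 and SBPASE at -0.93. The length-adjusted medians were -0.78, -0.87 and -0.77 in that order. Without scaling between arrays 12 of the 18, 17 of the 27 and 11 of the 17 genes were lower, and with normexp and quantile normalization 17, 26 and 16 were. The medians without scaling were near 0, at -0.08, -0.04 and -0.04, while that of all genes was 0.49. These lists were thus lower relative to other genes, and the size of a decrease in itself depends on the scaling. Members of the light-harvesting family are close in sequence, so their separate values are uncertain.

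Chlorophyll synthesis genes were lower as a group, and genes of chlorophyll breakdown and leaf senescence higher. Of 23 synthesis genes 22 were lower, 8 of them at least 2-fold, with a median of -0.70 (percentile 0, length-adjusted -0.75). DVR (AT5G18660), a reductase gene of the late pathway, was 4.96-fold lower (-2.31, error 0.20). GUN5, which encodes the large subunit of magnesium chelatase, was 4.05-fold lower, and HEMA1, for the entry step of the pathway, 3.34-fold lower. The GUN5 transcript is long, and its length-adjusted difference was -0.93. GUN4, whose product stimulates that chelatase, stood at -0.51, and LIN2 at 0.26 was the 1 gene above 0 with this scaling. Without scaling 17 of the 23 were lower. The senescence list had a median of 0.70 over 17 genes (percentile 99.8, length-adjusted 0.51), with 6 genes at least 2-fold higher and 0 at least 2-fold lower. SAG13 was 4.21-fold higher, the stay-green gene NYE2 4.17-fold higher and SAG21 3.95-fold higher, whereas NYE1 stood at 0.40, ORE1 at -0.21, and NAP and NYC1 both at -0.29. SAG12, a marker of late senescence, was not well above background on either array. The median of this list was 0.40 (percentile 93.9) when only brighter probes were used.

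Genes for the plastid's own gene expression were lower on the kanamycin array, while cytosolic ribosome genes did not stand apart. All 36 nuclear genes for plastid ribosomal proteins were lower, with a median of -0.51 (percentile 0, length-adjusted -0.93), from PRPL5 (AT4G01310) at -1.22 and PSRP2 at -1.21 to PRPS9 at -0.08. Without scaling, 23 of the 36 were lower and the median was -0.07. The list of plastid transcription and translation factors had the lowest median of the 31 lists fixed beforehand, -1.32 over 14 genes (percentile 0, length-adjusted -0.97), and 9 of its genes were at least 2-fold lower. SCO1, a plastid elongation factor gene, was 4.79-fold lower (-2.26, length-adjusted -1.59), the plastid RNA polymerase gene SCA3 4.61-fold lower (-2.20, length-adjusted -1.28), and HMR (AT2G34640), for a component of the plastid transcription machinery, 4.05-fold lower. SIG5, a plastid sigma factor gene, stood at -1.12 (error 0.20), whereas GLK1 and GLK2, regulators of photosynthesis genes, stood at 0.30 and -0.01. The 17 cytosolic ribosomal genes had a median of 0.10 (percentile 50.6), which turned to -0.27 (percentile 15.0) after length adjustment, from RPL3A at -0.65 to RPL16A at 0.71.

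Transcripts of the plastid genome were lower too, whereas those of the mitochondrial genome, many of them dim, did not stand apart. The 97 probes that the array places on the plastid genome had a median of -0.66 (percentile 0 among 2000 random probe lists), with 93 below 0, 32 at least 2-fold lower and 0 at least 2-fold higher. Without scaling their median was -0.22, with 71 below 0. No length adjustment was made for these probes, so what the length trend adds to their values was not tested. Chosen after their values were seen, the 3 probes for the photosystem I apoprotein A1 stood at -1.79, -1.78 and -1.66. A probe for the alpha subunit of the plastid-encoded RNA polymerase (chromosome C, 78512 to 78571) stood at -1.63, and 1 for ribosomal protein S12 at -1.60. For the photosystem II protein that carries the quinone B site, 2 probes read -0.26 and 0.08. The 113 mitochondrial genome probes had a median of 0.15 (percentile 85.2), with 43 below 0, 3 at least 2-fold higher and 2 at least 2-fold lower. Without scaling their median was 0.59, with 17 below 0. Many of them were dim, under the median level of measured genes (-1.12). The brightest on the control array, in falling order of level, stood at -0.54, -0.73, -0.43, -0.34 and 0.11. The probes at -0.43 and -0.34 are described in the array files as ribulose-bisphosphate carboxylase. A plastid genome probe for the large chain of that enzyme stood at -0.55, and which RNA the former probes read was not tested. Those next in level, also over -1.12, stood at 0.57, 0.30, -0.10, 0.23 and 0.42. Values above 0 were therefore not confined to dim probes.

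Jasmonate and ethylene genes had the highest median of those lists. All 29 were higher on the kanamycin array under every scaling tried, 23 of them at least 2-fold, with a median of 2.35 or 5.12-fold (percentile 100, length-adjusted 2.3). With only brighter probes kept the median was 1.3 (percentile 100). PR3 (AT3G12500), a basic chitinase gene, was 144-fold higher (7.17, error 0.24) over 2 probes with an SD of 0.08. JAZ10 and JAZ8, repressor genes that jasmonate itself induces, were 31.3-fold and 28.5-fold higher. The smallest differences were those of LOX3 at 0.66, JAZ1 at 0.55 and LOX2, a lipoxygenase gene of jasmonate synthesis, at 0.13. Salicylic acid defence genes were higher by less, with a median of 0.57 over 20 genes (percentile 99.4, length-adjusted 0.56), and 9 were at least 2-fold higher. EDS5, a gene of the salicylic acid pathway, was 5.10-fold higher, the glutaredoxin gene GRXC9 4.25-fold higher and the marker gene PR1 3.59-fold higher (1.85, error 0.20). ICS1, for the main salicylic acid synthesis enzyme, stood at 0.02, NPR1 at -0.08, and EDS1 was 2.47-fold lower.

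Detoxification and sulfur-rich defence compounds formed the next groups. All 16 measured detoxification genes were higher, 14 at least 2-fold, with a median of 1.65 (percentile 100, length-adjusted 1.4), and 2 more were well above background on the kanamycin array only. The glutathione transferase genes GSTU24, GSTU4 and GSTU1 were 8.90-fold, 7.09-fold and 5.36-fold higher, and GSTF2, GSTU19 and GSTF8 stood at 1.22, 0.76 and 0.40. Members of this family are close in sequence, so single values are uncertain. All 17 glucosinolate and camalexin genes were higher, 9 at least 2-fold, with a median of 1.15 (percentile 100, length-adjusted 1.19). BCAT4 and BAT5, of the aliphatic glucosinolate pathway, were 7.32-fold and 4.63-fold higher, and PAD3, for the last step of camalexin synthesis, was 3.47-fold higher. The regulator genes MYB28 and MYB29 stood at 0.31 and 0.26, and CYP79B3 at 0.49. No scaling changed the direction of a member of either list. The sulfur starvation list had a median of 0.73 over 8 genes (percentile 99.2, length-adjusted 0.51), and lost its place above the random lists without the filter on dim probes (percentile 97.2) and with brighter probes (96.3). Its members went both ways: LSU1 was 2.36-fold higher, the sulfate transporter gene SULTR1.2 2.23-fold higher and LSU2 stood at 0.85, whereas APR2, SDI1 and APR3 stood at -0.75, -0.68 and -0.45.

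**Figure D2:**
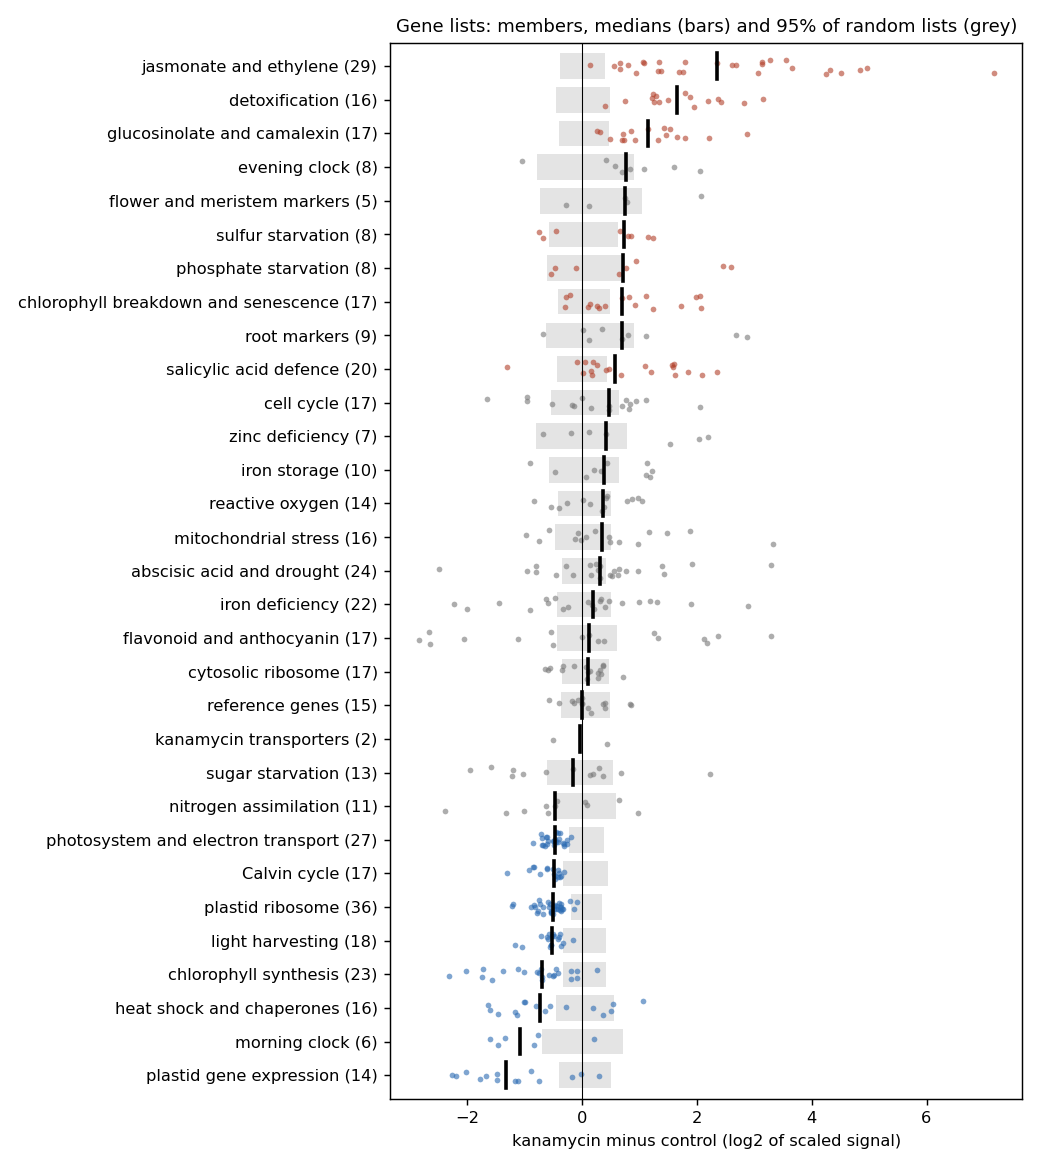
Differences between kanamycin and control (log2 of scaled signal, horizontal axis) for the members of each of the 31 lists, with the number of measured genes in parentheses. Each point is a gene, black bars are list medians, and grey boxes hold 95% of the random lists matched on level; red and blue points belong to lists above and below that range. Jasmonate and ethylene genes reach a median of 2.35 and plastid gene expression genes a median of -1.32.

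Of the transporters tied to kanamycin, ABCG19 (AT3G55130), a vacuolar transporter gene, stood at 0.43 (error 0.20) and MAR1 (AT5G26820), a plastid transporter gene, at -0.51 (error 0.20). Neither reached 2-fold. Iron deficiency genes went both ways, with a median of 0.20 over 22 genes (percentile 73.2). The regulator genes BHLH100 and BHLH38 were 4.70-fold (-2.23, error 0.34) and 4.02-fold lower (-2.01, error 0.34), BHLH39 was well above background on the control array only and at least 1.89-fold lower with kanamycin, and BHLH101 stood at -0.33. BTSL2 (AT1G18910) was 2.72-fold lower (-1.44, length-adjusted -0.40). In contrast NAS1, a nicotianamine synthase gene, was 7.43-fold higher, F6H1, for coumarin synthesis, 3.72-fold higher and MYB10 2.48-fold higher. The root iron transporter gene IRT1 was not well above background on either array. In the iron storage list (median 0.38 over 10 genes, percentile 84.9, length-adjusted 0.58 at percentile 98.5), VTL1, the ferritin gene FER1 and VTL2 were 2.33-fold, 2.26-fold and 2.18-fold higher, while FER3 stood at -0.47, NEET at -0.91 and YSL3 at 0.08. The zinc deficiency list had a median of 0.42 over 7 genes (percentile 85.6), or 0.93 at percentile 99.45 without the filter on dim probes. Its zinc transporter genes ZIP9, ZIP1 and ZIP5 were 4.56-fold, 4.09-fold and 2.88-fold higher, and HMA2, ZIP3 and BZIP23 stood at -0.69, -0.19 and 0.12.

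Flavonoid and anthocyanin genes went both ways. The list median was 0.13 over 17 genes (percentile 55.9), with 6 genes at least 2-fold higher and 5 at least 2-fold lower. FLS1, 4CL3 and CHS were among the lowest genes, as given above, whereas DFR, the dihydroflavonol reductase gene of the anthocyanin branch, was 9.77-fold higher (3.29, error 0.29). The anthocyanin regulator gene PAP1 was 5.18-fold higher and UF3GT 4.49-fold higher. DFR and UF3GT were dim on the control array, and with only brighter probes kept the median of the list turned to -0.83 (percentile 0.33).

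Nutrient and sugar lists were mixed. The phosphate starvation list had a median of 0.71 over 8 genes (percentile 98.1, length-adjusted 0.71). PAP17, a phosphatase gene, was 6.05-fold higher, SPX1, a phosphate sensor gene, 5.46-fold higher and MGD3 stood at 0.94, while SQD2, MGD2 and SQD1 stood at -0.53, -0.47 and -0.10. This list lost its place above the random lists with normexp (percentile 96.3 with quantile normalization) and with brighter probes (80.8). The nitrogen assimilation list had a median of -0.48 over 11 genes (percentile 2.66, length-adjusted -0.15 at percentile 29.7). GLU1, for the main leaf glutamate synthase, was 5.25-fold lower (-2.39, length-adjusted -1.22), GLN2, for the plastid glutamine synthetase, 2.51-fold lower and the nitrate reductase gene NIA1 2.02-fold lower (-1.01, length-adjusted -0.21), whereas GDH2 stood at 0.97, NRT2.1 at 0.64 and GLN1.1 at 0.09. The sugar starvation list had a median of -0.15 over 13 genes (percentile 30.1), from TPS11, DIN9 and DIN10, which were 3.86-fold, 3.01-fold and 2.34-fold lower, to ATL8, 4.69-fold higher, with KMD1 at 0.67 and TPS10 at 0.37. TPS11 and DIN10 stood at -1.23 and -0.52 after length adjustment.

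Heat shock and chaperone genes were lower as a group, with a median of -0.72 over 16 genes (percentile 0.14, length-adjusted -0.40), and 6 were at least 2-fold lower. The lowest were genes for plastid chaperones: CLPB3 was 3.11-fold lower (-1.64, length-adjusted -0.78), CPN60A 3.04-fold lower and HSP70-6 2.75-fold lower. The cytosolic HSP70-4 was 2.1-fold higher, and HSFA7A and HSP18.2 stood at 0.53 and 0.51. The other stress lists did not stand apart. Mitochondrial stress genes had a median of 0.34 over 16 genes (percentile 89.2), in which the alternative oxidase genes AOX1D and AOX1C were 9.99-fold and 3.67-fold higher and UGT74E2 2.80-fold higher, while AOX1A stood at 0.22 (error 0.20), NAC013 at -0.58, DIC2 at -0.75 and NDA1 at -0.97. Reactive oxygen genes had a median of 0.36 over 14 genes (percentile 88.9). The superoxide dismutase gene CSD1 was 2.07-fold higher, with APX1 at 0.98 and CAT3 at 0.87, and the catalase gene CAT2 stood at -0.84, FSD2 at -0.54 and FSD3 at -0.40. Abscisic acid and drought genes had a median of 0.31 over 24 genes (percentile 90.4). HAI1, a phosphatase gene of abscisic acid signalling, was 9.79-fold higher, RD29B 3.79-fold higher and LTI30 2.69-fold higher, whereas the cold regulator gene CBF1 was 5.60-fold lower, with CBF2 at -0.96 and RD29A at -0.80.

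Lists for harvest time, cell division and organ makeup gave the following. Morning clock genes had a median of -1.08 over 6 genes (percentile 0.16, length-adjusted -0.92): PRR7 was 3.04-fold lower (-1.61, length-adjusted -0.95), PRR9 2.75-fold lower and CCA1 2.53-fold lower, with CDF1 at -0.83, LHY at -0.77 and RVE8 at 0.20. Of 8 evening clock genes 7 were higher, with a median of 0.77 (percentile 95.1, length-adjusted 0.92 at percentile 98.3). ELF4 was 4.13-fold higher, GRP7 3.05-fold higher and BOA 2.1-fold higher, with FKF1 at 0.58 and TOC1 at 0.42, while GI was 2.06-fold lower and had a length-adjusted difference of -0.01. Cell cycle genes had a median of 0.47 over 17 genes (percentile 92.1). The kinase genes CDKB1.1 and CDKB2.1 were 4.13-fold and 2.15-fold higher and CYCB1.3 stood at 0.94, whereas MCM2 was 3.14-fold lower (-1.65, length-adjusted -0.84), with CDC6 and MCM5 both at -0.96. Root markers had a median of 0.69 over 9 genes (percentile 92.9), in which the phosphate transporter genes PHT1.1 and PHT1.4 were 7.29-fold and 2.15-fold higher, the endodermis gene CASP1 6.39-fold higher, SHR stood at 0.11, LRX1 at 0.02 and SCR at -0.69. Flower and meristem markers had a median of 0.75 over 5 genes (percentile 91.6), with PI 4.22-fold higher, SOC1 at 0.79, FUL at 0.75, AG at 0.12 and SEP3 at -0.29. The median of 15 reference genes was 0.00 (percentile 33.9), from ACT2 at -0.58, PP2AA3 at -0.40 and TUB2 at -0.18 to YLS8 at 0.41, UBC21 at 0.84 and UBC9 at 0.85. As this median follows the scaling, its sign carries no direction.

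In all, 7 of the 30 lists with a percentile stood above the random lists and 8 below. About 1.5 would do so if genes moved independently. Genes of a pathway move together, and the random lists were not matched on transcript length. These counts are therefore not a test against chance.

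Some genes were well above background on 1 array only. On the kanamycin array only there were 454 such genes, of which 390 had a bound of at least 2-fold and 214 of at least 4-fold. The gene AT4G33070, which encodes pyruvate decarboxylase 1 of alcoholic fermentation, was at least 366-fold higher with kanamycin. AT2G15780 was at least 328-fold higher, the zinc finger gene ZFP5 at least 325-fold higher, AT5G10040 at least 323-fold higher and AT5G66985 at least 294-fold higher. On the control array only there were 1309 genes, but the background was noisier on the other array: 96 of these had a bound of at least 2-fold, 9 of at least 4-fold, and for 621 no fold is given. The largest bounds were those of SCPL22 (AT2G24000), at least 10.2-fold lower with kanamycin, AT5G15430 (6.81-fold), AT1G19210 (5.54-fold), the plastid acetyl-CoA carboxylase gene ACC2 (5.47-fold) and AT3G20200 (5.40-fold).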

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

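The comparisons above use probes tied to a gene locus. Among the 3239 probes without a locus that were well above background on both arrays, 406 were at least 2-fold higher and 265 at least 2-fold lower on the kanamycin array, with a median difference of 0.05. They drew attention as a signal in data that the gene comparisons leave out.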

How the results depend on the processing

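The spike-in scaling and the length adjustment were chosen after seeing the data, and the other settings before the data were examined. For the gene lists, 4 of 12 settings test nothing: median scaling, no scaling and spike-in scaling shift every gene alike, and no spot was saturated, so no percentile can move. In the other 8 settings 222 of 236 percentiles stayed on the same side of the random lists. No percentile was taken for the pair of transporters, or with brighter probes for cell cycle, root, flower and evening clock. Of 2380 combinations of a named gene and a setting, 423 moved by at least the scanner-model error: all 203 named genes without scaling, 120 of 203 after length adjustment, 43 and 33 with normexp (quantile and 75th percentile) and the rest when probes were filtered or combined otherwise. No named gene past 2-fold changed sign. No paired analysis was possible because each group has 1 array, and leaving out an array was not possible for the same reason. The count of higher genes was 5434 without scaling, 950 with brighter probes only, 5222 at 1.5-fold and 759 at 4-fold. That of lower genes was 902, 1315, 4868 and 164 in the same order, and 1489 after length adjustment. Brighter probes and the thresholds change what is counted by construction, and missing scaling adds 0.44 to every difference. With spike-in scaling 2982 genes were higher and 2141 lower. The nitrogen list passed below the random lists at -0.55 with normexp and quantile normalization, -0.49 with normexp and the 75th percentile, -0.53 with brighter probes and -0.49 with the mean over probes. The phosphate list fell inside their range at 0.54 and 0.65 with both normexp settings and at 0.34 with brighter probes. The sulfur list did so at 0.67 without the filter on dim probes and with brighter probes, and the senescence list at 0.40 with brighter probes. The zinc list passed above at 0.93 without that filter, iron storage at 0.58 and the evening clock at 0.92 after length adjustment, and the flavonoid list turned to -0.83 with brighter probes. Medians inside the range of random lists changed sign for sugar starvation (0.29 without scaling), flavonoids (-0.06 with normexp and quantile normalization), mitochondrial stress (-0.02 with brighter probes), cytosolic ribosomes (-0.27 after length adjustment) and reference genes (at 0 in both, brightest probe). So did those of root markers (-0.32 with brighter probes) and of the transporters (0.41 without scaling, 0.04 with spike-in scaling, 0.43 after length adjustment). For these lists the cause was not tested. Leaving out saturated spots and the stricter detection call (454 and 1309 genes on 1 array only, as before) removed nothing and so test nothing. A noisier background on the kanamycin array limits what can be said of genes dim there.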

Other observations

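The tests of the 12 low-oxygen genes not yet seen, of the second clock sets, of the second jasmonate set and of the genes outside plastid functions were written before their values were seen, and the other tests in this part after. The gene sets of this part were drawn up after the main results were seen.

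Genes of the low-oxygen response were among the highest on the kanamycin array. All 16 measured genes of this set were higher, 15 of them at least 2-fold, with a median of 3.67 (percentile 100, length-adjusted 3.55). SUS4, a sucrose synthase gene, stood at 6.48 (error 0.22), the desaturase gene SAD6 at 7.66, the transcription factor gene LBD41 at 5.89 and the oxygen-sensing cysteine oxidase genes PCO2 and PCO1 at 5.77 and 3.74. ACO1, for ethylene synthesis, stood at 5.51, PDC2 at 2.68 and the haemoglobin gene HB1 at 3.37. PDC1 was at least 366-fold higher and HRE2, a transcription factor gene of this response, at least 52.0-fold higher. SUS1, ETR2 and LDH1 stood at 1.33, 1.34 and 1.58, and ALAAT1 at 0.89.

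Genes of photorespiration, which recycles a by-product of carbon fixation through chloroplast, peroxisome and mitochondrion, were lower as a group. Of 13 genes 12 were lower, 6 at least 2-fold, with a median of -0.92 (percentile 0, length-adjusted -0.70 at percentile 0.365). SHM1 had been seen before the set was drawn up, and the other 12 genes had a median of -0.87, with 5 at least 2-fold lower (length-adjusted -0.63 at percentile 0.7). SHM1, for serine hydroxymethyltransferase, stood at -2.41 (error 0.20), and the glycine decarboxylase genes GLDP1 and GLDP2 stood at -1.59 and -1.43, or -0.70 and -0.49 after length adjustment. HPR stood at -1.46 and AGT at 0.08.

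A low-oxygen response in the treated plants, for example in wet soil around poorly growing roots, is a hypothesis for the first of these groups. ADH1, HB1, HRA1 and WIP4 had drawn attention to this set, and without them the 12 measured genes whose values had not been seen when it was drawn up had a median of 3.21 (percentile 100), as that hypothesis needs. Genes of a pathway move together, so these 12 are not independent of the genes that drew attention. A larger share of root tissue in the treated sample might raise some of the same genes, though the design text describes RNA from leaves, which would exclude roots, while the tissue label reads seedlings. The root markers had a median of 0.69 over 9 genes, inside the range of random lists, with 8 above 0, PHT1.1 at 2.87, CASP1 at 2.68 and SCR at -0.69, and the median turned to -0.32 with brighter probes, which left fewer than 3 of them, so this stays open. Neither explanation says whether kanamycin, the pot or the slide is behind the difference, since there was 1 of each per group.

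Genes with long transcripts were lower on the kanamycin array, from a median of 0.53 for genes whose farthest probe lies within 500 nt to -1.06 beyond 3000 nt, where 54.8% of 1128 genes were at least 2-fold lower. If copying starts at the 3' end, RNA that was broken or copied short would lower the 5' probe of a transcript more than its 3' probe. For the 1057 transcripts with probes over 1000 nt apart, the median difference was instead 0.14 in favour of the 5' probe (bootstrap interval 0.11 to 0.16). That interval holds the spread between transcripts of 1 pair of arrays, not between extractions. Broken RNA copied from other start points is not covered by this comparison. Probe GC content does not account for the length trend, as rho with probe position was -0.44 among probes of equal GC against -0.43 among all. Nor do plastid genes carry it, as rho was -0.50 over 19299 genes left after those described as plastid genes and the members of the lists were taken out. Loss of whole long RNA molecules before labelling and an effect of the treatment itself both stay open and were not tested, as there was 1 extraction per group.

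The shift of the jasmonate genes, and the opposite shift of the plastid lists, could in principle follow from the length trend, but the length-adjusted median of the jasmonate list was 2.3, and the light-harvesting, photosystem, plastid ribosome and chlorophyll synthesis lists all stayed below the random lists. A response to wounding or an attacker in the single treated pot is a candidate explanation for the jasmonate part. In a second set of 10 jasmonate-induced genes, 5 were at least 2-fold higher and 1 was below 0. They ran from TPS4 at 3.81 and CYP94C1 at 2.96 to ACX1 at 0.36 and JAM1 at -0.11. The median of the set was 1.13 (percentile 99.96), which such a response needs. Kanamycin acting through the same hormone would give that value as well, so the treatment stays open as a biological explanation that these arrays did not test.

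Morning clock genes were lower and most evening clock genes higher, and a later hour of harvest for the treated pot is a hypothesis that might account for it. A second set of 7 morning genes had a median of -1.05 (percentile 0.13, length-adjusted -0.47 at percentile 6.99). Of these 6 were lower, from LNK2 at -1.45, and RVE2 stood at 0.24. A second set of 6 evening genes had a median of 0.54 (percentile 88.9), inside the range of random lists, so these few genes leave the hypothesis open. With 1 pot and 1 array per group, harvest time and treatment could not be told apart in any case. Hour of harvest is not given in the sources used here.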
